A study of Homo sapiens with 4 samples.

How the data were processed

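RNA was measured in 4 libraries of lung progenitors derived from the human embryonic stem cell line RUES2, 1 each of the day 12 control, the day 15 control, the day 15 library labelled CHIR99021 and the day 15 library labelled IWP2. Per the labels' protocols, the medium from day 6 held 3 µM CHIR99021, 10 ng/ml each of FGF10, FGF7 and BMP4, and 50 nM all-trans retinoic acid, IWP2 was used at 1 µM from day 12, and cells analysed on day 15 had been replated on day 10. The labels do not say whether the day 12 control was replated as well. Per the labels' protocols, libraries were made from 100 to 200 ng of total RNA with poly(A) selection and a kit that does not mark strand, so overlapping genes on opposite strands share fragments.

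Per the submitters' processing notes, TopHat2 2.0.14, Bowtie2 2.2.3, Cufflinks 2.2.1 and Cuffdiff were used, with no version for the last and no roles or order given. Those notes list the mouse build mm10, but the files hold human gene identifiers, and 97.5% of the 58067 genes found in GENCODE 29 had the same chromosome, start and end there, so coordinates are given on GRCh38. The annotation release is not given in the sources used here. Per the file headers, the authors deposited for each library the FPKM of every gene (fragments per kilobase of transcript per M (mega) mapped fragments) with a lower and an upper limit. Per the file headers, the authors also deposited p-values and q-values for each pair of libraries, for genes, isoforms and start-site groups. The 6 columns of FPKM values and the log2 fold changes of those tables were not used here, because the library names d15 and d15c do not show which is the day 15 control.

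Each file held 58424 gene rows. After 3 genes with a failed estimate (CCNA2, EXOSC9 and PAICS) and 91 repeated rows were dropped, 58330 genes remained. CCNA2 was thereby missing from the cell cycle list. Log2 ratios were computed as log2((FPKM + 1)/(FPKM + 1)). A gene counted as higher or lower when it was at least 2-fold apart on that scale with 1 FPKM or more in the higher library. The limits were taken as FPKM ± 2 SD, and the SE of a log2 ratio was propagated from them. A limit of 0 around an FPKM of 0 adds no error, so the SE is too small where a gene is listed at 0. No model was fitted and no p-value was made, because each group had 1 library.

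Depth was estimated. For genes with a single transcript the limits imply a fragment number, (2 × FPKM/(upper limit − FPKM)) squared, and 24.9 to 26.8% of these numbers per library lay within 0.02 of a whole number where genes with several transcripts gave 4.02 to 4.60%. Among those with 3000 bp or more, the fragment number and FPKM gave the total per library, with a median of 20.6 M (mega, quartiles 20.4 to 20.9) for the day 12 control, 18.8 M (18.7 to 19.1) for the day 15 control, 17.1 M (17.0 to 17.4) for the library labelled CHIR99021 and 16.8 M (16.6 to 17.0) for the library labelled IWP2. These totals are estimates.

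Before the data were examined, 20 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. The lists covered Wnt targets, Wnt ligands, lung epithelial progenitors, alveolar and airway epithelium, thyroid, pharynx and oesophagus, stomach with liver, pancreas and gut, pan-epithelial genes, mesenchyme, neural genes, endothelium and blood, pluripotency, cell cycle, BMP, FGF and retinoic acid targets, the Notch pathway, p53 and stress, and housekeeping genes. A further 6 lists were chosen after the data had been seen. Each list's median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn gene by gene from the 200 genes nearest in mean FPKM. This percentile describes these libraries only. Random members were drawn separately, while members of a list may vary together, which can place a median outside the random range more often. It is thus not a p-value. The rule named, per comparison, the 8 highest and 8 lowest genes with 5 FPKM or more in the higher library, a 2-fold difference and intervals apart, leaving out mitochondrial genes, genes of ribosomal, small nuclear, small nucleolar and micro RNA, and rows without a gene name. Other short RNA genes were not left out. In the report, APOA2 and FOXE1 were named after their values had been seen. It also named 10 genes always (AXIN2, LEF1, NKD1, NOTUM, SP5, NKX2-1, FOXA2, SOX9, SOX2 and SFTPC) and up to 4 members per list that met the same limits.

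Alternatives were a pseudocount of 0.1, no FPKM minimum, a minimum of 5 FPKM, libraries scaled so that the median log2 difference of genes expressed in all was 0, values scaled to TPM, and genes with intervals apart. Protein-coding genes alone, and for lists other than Wnt targets and lung progenitors all alternatives, were added after the data had been seen. For every list the median over members at 1 FPKM or more in the higher library was taken as well. Overlap of the treated libraries was compared with 100 simulations in which 2 unchanged libraries were drawn against 1 shared control with noise from the intervals. The counts of genes higher and lower were likewise compared with 100 simulations per comparison of a pair of unchanged libraries, drawn around their mean with noise from the intervals, a check added after the data had been seen. The simulated noise leaves out the spread between cultures. The steps were tested on simulated data of 58330 genes. In each comparison 100 genes at 5 FPKM or more were changed by a log2 of 2 and 100 by a log2 of 3. Recovery of genes below 5 FPKM was not tested. Of those changed by 2 and by 3, 99% and 100% were recovered for the library labelled CHIR99021 against the day 15 control. The shares were 98% and 99% for the library labelled IWP2 against the day 15 control. They were 100% and 99% for the library labelled IWP2 against that labelled CHIR99021. For the day 15 against the day 12 control they were 98% and 100%. In the order of these comparisons 1.43%, 1.53%, 1.56% and 1.28% of the unchanged genes at 5 FPKM or more were called as well. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.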

Results

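Messenger RNA was sequenced from lung progenitor cells that had been derived from RUES2, a human embryonic stem cell line. The progenitors are marked by NKX2-1, the transcription factor that specifies lung and thyroid endoderm. Per the labels' protocols, they were kept from day 6 to day 15 in a medium with CHIR99021, an inhibitor of the kinase GSK3 that serves as an agonist of Wnt signalling, together with FGF10, FGF7, BMP4 and all-trans retinoic acid. At day 12 part of the cultures went for 3 days into a medium without CHIR99021, or without CHIR99021 and with IWP2, which blocks the production of Wnt ligands. The question was whether Wnt signalling through beta-catenin keeps the progenitors in their state once lung fate has been set. There were 4 libraries, 1 per group, namely the day 12 control, the day 15 control, a day 15 library whose treatment label reads CHIR99021, and a day 15 library labelled IWP2. The design text speaks of withdrawal of the agonist while the label names the agonist itself. Of the media described above, the one without CHIR99021 and without IWP2 would otherwise have no library, which points to withdrawal. The label does not say so, so that library is called "the library labelled CHIR99021" throughout, and no direction of treatment is assumed for it.

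With 1 library per group, no difference had a replicate check, and no p-value was computed. The errors given are the authors' quantification intervals, which cover the assignment and counting of fragments in 1 library and not the spread between cultures. Log2 ratios were taken on FPKM + 1, which understates the differences of low genes, and their SE comes from those intervals. The intervals implied depths of about 20.6 M (mega) fragments in the day 12 control, 18.8 M in the day 15 control, 17.1 M in the library labelled CHIR99021 and 16.8 M in the library labelled IWP2. Between 14922 and 15642 genes reached 1 FPKM per library. Ribosomal protein genes made up 22.7% of all FPKM in the day 12 control, 29.2% in the day 15 control, 17.8% in the library labelled CHIR99021 and 15.3% in the library labelled IWP2. Small RNA genes, whose FPKM is unstable because of their short length, took 9.13%, 6.49%, 13.0% and 14.1% in the same order.

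NKX2-1 (ENSG00000136352.17, GRCh38 chromosome 14, 36516392 to 36521149) stood at 99.7 FPKM in the day 12 control and at 70.7 FPKM in the day 15 control (interval 67.0 to 74.4). It was at 13.8 FPKM in the library labelled CHIR99021 (12.3 to 15.3) and at 8.03 FPKM in the library labelled IWP2 (6.85 to 9.20). AXIN2, a feedback inhibitor and direct target of Wnt signalling (ENSG00000168646.12, chromosome 17, 65528563 to 65561647), was at 7.32 FPKM in the day 12 control (6.27 to 8.37) and 7.73 FPKM in the day 15 control (6.73 to 8.72). It stood at 2.48 FPKM in the library labelled CHIR99021 (1.76 to 3.20) and 2.49 FPKM in the library labelled IWP2 (1.76 to 3.22). Since the library kit did not mark strand, fragments of antisense transcripts at the NKX2-1 locus were not separable from those of NKX2-1.

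**Figure D1:**
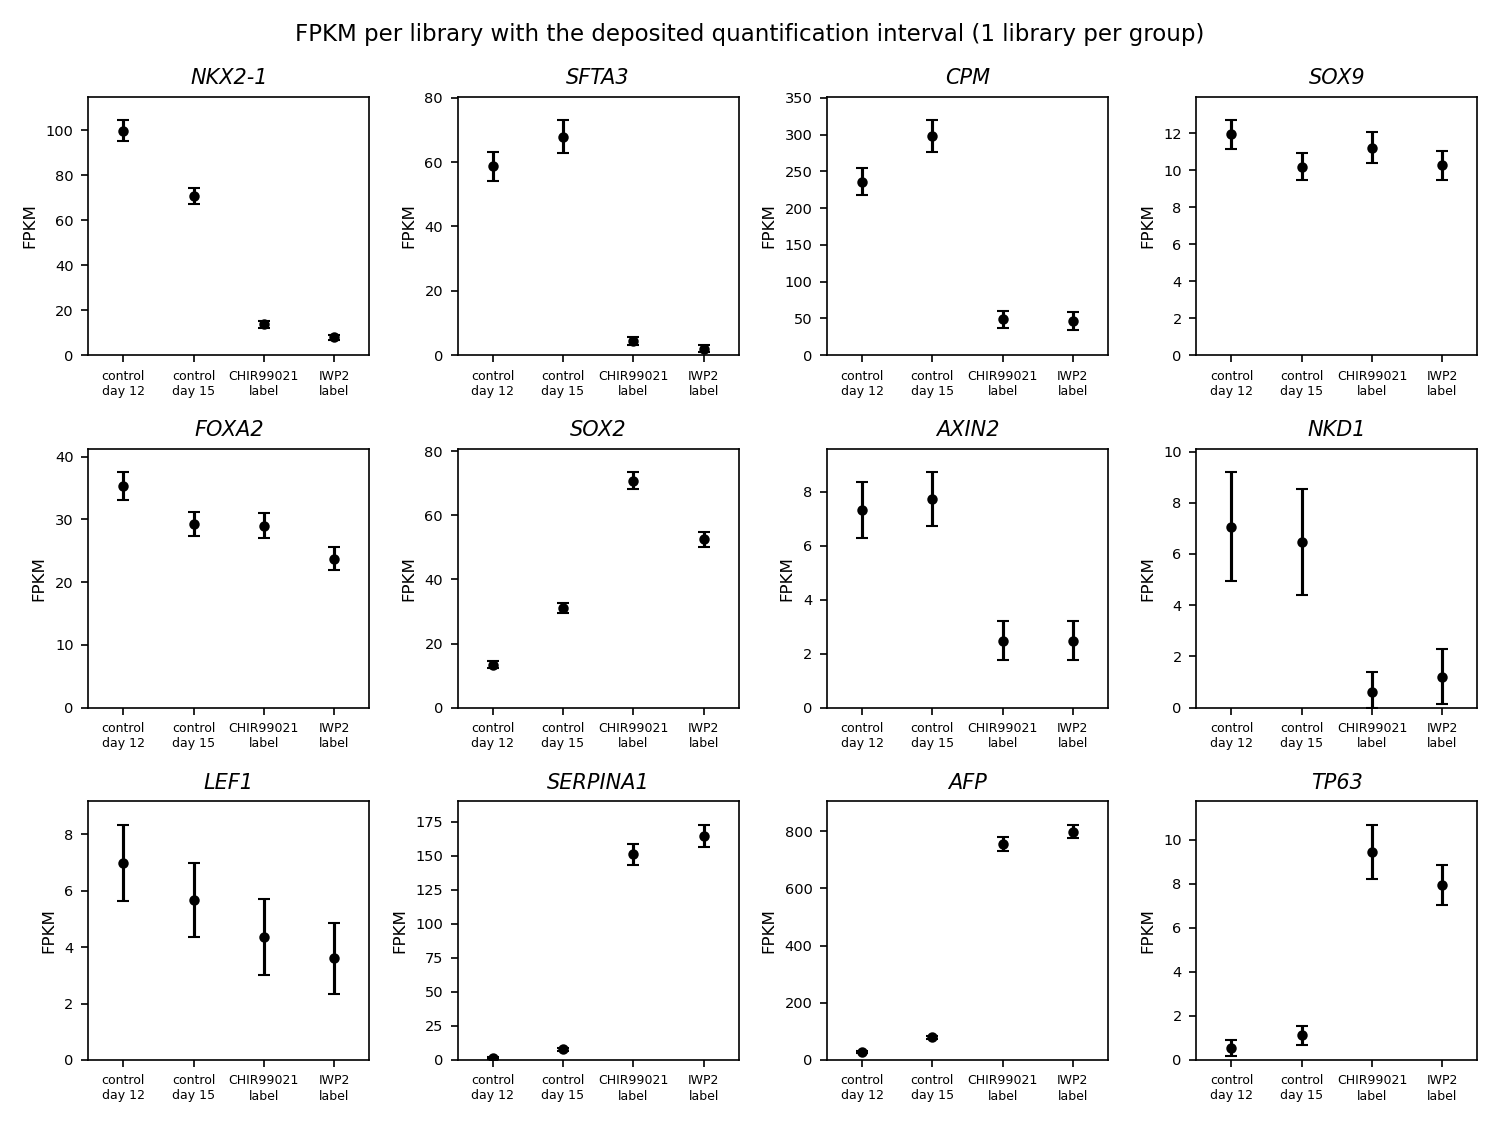
FPKM of 12 genes in the 4 libraries, on a linear y axis from 0, where each point is 1 library and the bars span the quantification interval deposited by the authors. NKX2-1 stood at 70.7 in the day 15 control against 13.8 and 8.03 in the libraries labelled CHIR99021 and IWP2, while SOX9 lay between 10.2 and 11.9 in all 4.

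The library labelled CHIR99021 was compared with the day 15 control for the genes that go with that treatment label. Several lung progenitor markers were lower. SFTA3, a surfactant-associated gene next to NKX2-1 (chromosome 14, 36473288 to 36513829), was at 4.47 against 67.9 FPKM (log2 -3.66, SE 0.18), CPM, a surface carboxypeptidase used to isolate lung progenitors, at 48.8 against 298 FPKM (log2 -2.59, SE 0.18), and NKX2-1 itself gave a log2 ratio of -2.28 (SE 0.08). The Iroquois factor IRX3 was at 1.32 against 6.94 FPKM. Of the 22 lung progenitor genes, 7 were at least 2-fold lower and 4 at least 2-fold higher, among them SOX2, a marker of proximal airway epithelium, at 70.8 against 31.1 FPKM (log2 1.16, SE 0.05). SOX9, a marker of the distal tip (log2 0.13, SE 0.07), and FOXA2, a factor of the whole endoderm (log2 -0.02, SE 0.07), had overlapping intervals. With members in both directions the list had a median log2 of 0.06, at percentile 36.5 of 10000 random lists of like expression, and a mean of -0.34. The sign of that median was the opposite, -0.06, when the libraries were scaled to a common median.

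Wnt target genes in the library labelled CHIR99021 had a median log2 of -0.21, at percentile 0.22 of the random lists, with 4 of 20 members at least 2-fold lower and 4 at least 2-fold higher. It was -0.32 when the libraries were scaled to a common median and -0.40 over members at 1 FPKM or more. The lower ones were WIF1, a secreted Wnt inhibitor, at 0.299 against 6.10 FPKM (log2 -2.45, SE 0.36), NKD1 at 0.599 against 6.48 FPKM (log2 -2.23, SE 0.41), AXIN2 (log2 -1.33, SE 0.17) and SP5, which was listed at 0 against 1.10 FPKM. NOTUM, a secreted Wnt deacylase, had a log2 ratio of -0.97, and LEF1, a nuclear effector, was at 4.37 against 5.68 FPKM with overlapping intervals. APCDD1, another Wnt inhibitor, was higher, at 41.3 against 6.64 FPKM (log2 2.47, SE 0.16). Wnt ligands had a median log2 of 0.30 (percentile 99.8), or 0.53 over members at 1 FPKM or more, with WNT11 at 12.0 against 2.71 FPKM and WNT5B at 10.2 against 2.71 FPKM.

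Several genes of other endodermal tissues were higher in the library labelled CHIR99021. The list of stomach, liver, pancreas and gut genes had a median log2 of 0.58 (percentile 99.96), with 6 of 16 members at least 2-fold higher and 1, APOA2, lower. Alpha-1-antitrypsin, SERPINA1, was at 151 against 7.67 FPKM (log2 4.13, SE 0.12), alpha-fetoprotein, AFP, at 756 against 79.1 FPKM (log2 3.24, SE 0.05) and the hepatic and intestinal factor HNF4A at 15.7 against 3.82 FPKM (log2 1.79, SE 0.12). HHEX, a factor of thyroid and liver buds, was at 33.8 against 6.07 FPKM, and TP63, the basal cell factor of airway and oesophagus, at 9.45 against 1.13 FPKM (log2 2.30, SE 0.17). Airway genes had a median log2 of 0.13 (percentile 97.5), with 5 of 15 at least 2-fold higher. Pan-epithelial genes had a median log2 of 0.83 (percentile 99.99), with 3 of 13 at least 2-fold higher, including KRT7 at 463 against 157 FPKM and CLDN6 at 696 against 260 FPKM. Mesenchymal genes had a median log2 of 0.37 (percentile 98.6), with 6 of 15 at least 2-fold higher, such as COL1A1 at 270 against 67.7 FPKM, and 1 lower, POSTN, at 8.01 against 27.4 FPKM. The Notch list had a median log2 of 0.42 (percentile 99.8), and its ligand JAG1 was at 29.2 against 5.38 FPKM. The BMP target list had a median log2 of 0.71 (percentile 99.96), with ID4 at 61.2 against 26.8 FPKM. Over members at 1 FPKM or more the medians were 0.88 for stomach, liver, pancreas and gut, 1.19 for airway, 0.95 for mesenchyme and 1.01 for Notch genes.

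The 8 highest genes in the library labelled CHIR99021 were CALB1, TM4SF4, CDH6, SCGN, ITIH2, VTN, HABP2 and SERPINA1. The cadherin CDH6 (chromosome 5, 31193750 to 31329146) was at 63.6 against 0.898 FPKM (log2 5.09, SE 0.13), the calcium sensor SCGN at 55.2 against 0.756 FPKM and the plasma adhesion protein vitronectin, VTN, at 88.3 against 2.04 FPKM. The 8 lowest were CYP1A1, IGFL2, TPPP3, SFTA3, ODAM, LINC02041, NELL1 and DIO1. CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, was at 1.00 against 39.6 FPKM (log2 -4.34, SE 0.16), and TPPP3, a tubulin-binding protein (chromosome 16, 67389809 to 67393535), at 61.5 against 886 FPKM (log2 -3.83, SE 0.06). LINC02041 was listed at 0. Retinoic acid targets had a median log2 of -0.17 (percentile 2.71), or -0.36 over members at 1 FPKM or more, with 4 of 15 at least 2-fold lower, while TGM2, at 46.8 FPKM, was higher (log2 2.41, SE 0.08). The p53 and stress list had a median log2 of -0.14 (percentile 4.74), or -0.24 under the common median and -0.09 as TPM, with ASNS at 19.3 against 53.9 FPKM and the near-identical HSPA1A and HSPA1B, whose fragments the quantification could share, both higher.

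Medians of further lists in the library labelled CHIR99021 were -0.04 for alveolar epithelium (percentile 12.2), 0.06 for pharynx and oesophagus (percentile 90.4), -0.01 for neural genes (percentile 18.0), 0.02 for endothelium and blood (percentile 89.8), -0.07 for pluripotency (percentile 13.4), -0.08 for FGF targets (percentile 8.26) and 0.00 for the thyroid (percentile 48.5). Under the common median those of alveolar and FGF genes were -0.07 and -0.19, and as TPM that of FGF genes was -0.03. Several of these lists held few expressed genes. Over members at 1 FPKM or more the medians were 0.40 for 8 alveolar, 0.55 for 2 pharynx and oesophagus, 0.92 for 3 neural, 0.02 for 6 pluripotency and 1.93 for 2 thyroid genes, and no endothelium or blood gene reached 1 FPKM. Both of those thyroid genes, HHEX and FOXE1, were at least 2-fold higher. In the alveolar list CAV1 and PDPN were at least 2-fold higher and SFTPC, the surfactant protein of type 2 cells, was listed at 0. Cell cycle genes had a median of 0.04 (percentile 28.9), which was -0.08 under the common median, and housekeeping genes one of -0.36 (percentile 8.33). In all, 1297 genes were at least 2-fold higher and 608 at least 2-fold lower of 16403 considered, and the intervals lay apart for 958 and 319 of them. Unchanged libraries simulated with noise from the quantification intervals gave 267 and 302 on average, and 16.8 and 17.3 with intervals apart. Higher genes were 68.1% of the calls, or 58.0% after scaling to a common median, and the median log2 of 13665 genes expressed in all libraries was 0.11 as deposited and 0.16 as TPM. Of the lower genes, 240 were protein-coding. Ribosomal protein genes took 17.8% against 29.2% of all FPKM, and small RNA genes 13.0% against 6.49%.

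**Figure D2:**
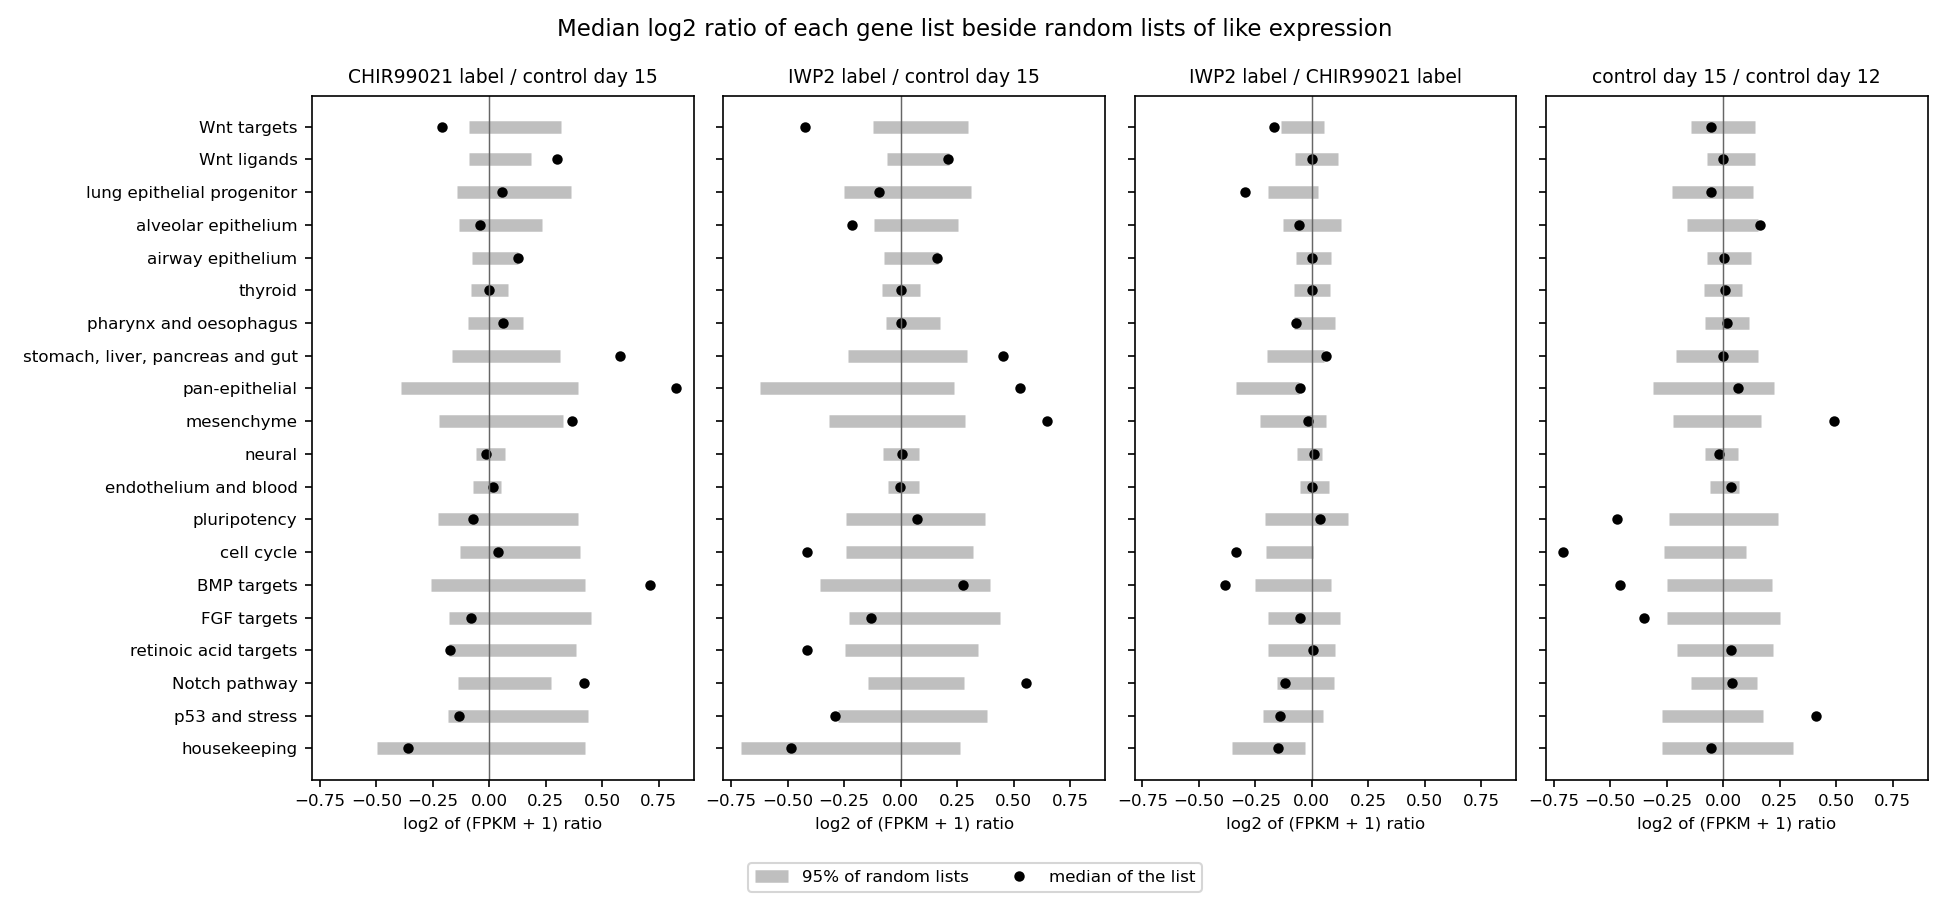
Median log2 ratio of the 20 gene lists in the 4 comparisons, where the x axis gives the log2 ratio of FPKM + 1, each black point is the median over the members of a list in 1 pair of libraries, and the grey bars span 95% of 10000 random lists of like expression. Wnt targets lay below the bars in both treated libraries, at -0.21 and -0.42, and within them between the controls, at -0.05.

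The library labelled IWP2, in which Wnt production was blocked per the protocol, was compared with the same day 15 control. NKX2-1 had a log2 ratio of -2.99 (SE 0.10), SFTA3 was at 2.01 against 67.9 FPKM (log2 -4.52, SE 0.25) and CPM at 46.4 against 298 FPKM (log2 -2.66, SE 0.19). Of the 22 lung progenitor genes, 8 were at least 2-fold lower and 4 at least 2-fold higher, with a median log2 of -0.10 at percentile 18.8 and a mean of -0.63. As TPM that median was 0.12. IRX3 was at 0.256 against 6.94 FPKM and ETV5, a factor downstream of FGF signalling, at 3.44 against 16.6 FPKM, while SOX2 was at 52.5 against 31.1 FPKM (log2 0.74, SE 0.05) and SOX9 had a log2 ratio of 0.01 (SE 0.07). FOXA2 was at 23.7 against 29.3 FPKM. Wnt targets had a median log2 of -0.42, at percentile 0.00, with 6 of 20 at least 2-fold lower and 2 higher, and as TPM the median was -0.23. WIF1 was at 0.0837 against 6.10 FPKM, NOTUM at 0.0947 FPKM (log2 -1.55), NKD1 at 1.21 against 6.48 FPKM (log2 -1.76, SE 0.40), and AXIN2 had a log2 ratio of -1.32 (SE 0.17). SP5 was listed at 0, LEF1 was at 3.61 against 5.68 FPKM with overlapping intervals, and APCDD1 was again higher, at 31.1 FPKM.

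Stomach, liver, pancreas and gut genes in the library labelled IWP2 had a median log2 of 0.45 (percentile 99.7), with 7 of 16 at least 2-fold higher and 1, APOA2, lower. The higher ones included SERPINA1 at 164 against 7.67 FPKM (log2 4.25, SE 0.12), AFP at 799 against 79.1 FPKM and HNF4A at 15.2 against 3.82 FPKM. HHEX was at 34.9 against 6.07 FPKM and TP63 at 7.94 against 1.13 FPKM. Pan-epithelial genes had a median log2 of 0.53 (percentile 99.8), mesenchymal genes 0.65 (percentile 100, 5 of 15 higher and 2 lower) and Notch genes 0.55 (percentile 100), with TAGLN at 367 against 69.0 FPKM and JAG1 at 26.9 against 5.38 FPKM. Wnt ligands stood at 0.21 (percentile 97.1), airway genes at 0.16 (percentile 97.4) and BMP targets at 0.28 (percentile 92.2). Cell cycle genes had a median log2 of -0.42 (percentile 0.08), although none of 21 was 2-fold apart. Retinoic acid targets, at -0.41 (percentile 0.22), and p53 and stress genes, at -0.29 (percentile 2.13), also had low medians. Their members went both ways, with 2 of 15 retinoic acid targets at least 2-fold lower and 1 higher, and 2 of 14 p53 and stress genes lower and 2 higher. Alveolar genes had a median of -0.22 (percentile 0.32), but 0.15 over the 8 members at 1 FPKM or more, of which 2 were at least 2-fold higher and none lower. Over such members the medians were 1.07 for stomach, liver, pancreas and gut, 0.83 for Wnt ligands, 1.18 for airway, 0.83 for Notch genes and 0.42 for BMP targets. As TPM, where the median of all expressed genes was 0.27 in place of 0.07, the medians were -0.19 for cell cycle genes, -0.25 for retinoic acid targets, -0.11 for p53 and stress genes, 0.51 for BMP targets and 0.28 for airway genes. Housekeeping genes had a median log2 of -0.48 (percentile 12.9), or -0.27 as TPM. Both values were lower than those of the cell cycle, retinoic acid and p53 lists, although within the housekeeping list's own random lists. Of the housekeeping genes, RPLP0, a ribosomal protein, was at 1174 against 2843 FPKM and B2M at 543 against 1144 FPKM, and ribosomal protein genes together took 15.3% against 29.2% of all FPKM.

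The 8 highest genes in the library labelled IWP2 were CDH6, ITIH2, VTN, CALB1, SCGN, TM4SF4, HABP2 and SERPINA1. CDH6 was at 75.1 against 0.898 FPKM (log2 5.33, SE 0.13) and VTN at 103 against 2.04 FPKM. The 8 lowest were IGFL2, CYP1A1, TPPP3, SFTA3, PVT1_1, ODAM, CRH and NELL1. TPPP3 was at 29.8 against 886 FPKM (log2 -4.85, SE 0.08), CYP1A1 at 0.388 against 39.6 FPKM, and CRH, corticotropin-releasing hormone, at 1.23 against 23.5 FPKM. PVT1_1 is a short RNA gene of a type that the rule for named genes did not leave out. It was listed at 0 with an interval of 0 to 0, against 12.6 FPKM with a lower limit of 0.191, so its place rests on the interval at 0. In all, 1225 genes were at least 2-fold higher and 856 at least 2-fold lower of 16501, with intervals apart for 909 and 562, where unchanged simulated libraries gave 283 and 301 on average, and 18.7 and 16.8 with intervals apart. Higher genes were 58.9% of the calls as deposited and 76.2% as TPM.

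Both treated libraries were set against the same control library, so chance values of that library enter both comparisons. A total of 800 genes was higher and 443 lower in both, and 18 were higher in one and lower in the other, among 16960 genes. Independent lists of these sizes would share 93.7 and 30.7 genes. Unchanged libraries simulated from the quantification intervals against 1 shared control shared 115 and 118 on average and at most 143 and 145. For genes at 5 FPKM or more the covariance of the log2 ratios across 11505 genes was 0.704 against 0.146 in the simulation, a difference of 0.558. The simulated noise left out the spread between cultures, and a single control library was not divisible. Part or all of the excess may therefore come from that shared library. Genes are not independent replicates.

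The libraries labelled IWP2 and CHIR99021 were compared directly with each other. Matrix metalloproteinase MMP9 was at 13.3 against 3.73 FPKM (log2 1.60, SE 0.12) and the chemokine CXCL12 at 8.69 against 2.24 FPKM (log2 1.58, SE 0.22). Only 5 further genes met the limits for the highest genes, namely S100A9, SSXP10, STX16-NPEPL1, GIPR and GOLGA8B. SSXP10 is a pseudogene, STX16-NPEPL1 a readthrough of neighbouring genes and GOLGA8B a member of a family of near copies, and their fragments are uncertain. The 8 lowest were CXCL14, METTL1, IFITM1, LDHA, ENDOG, DCN, IFIT1 and CRHBP. The chemokine CXCL14 was at 6.58 against 20.3 FPKM (log2 -1.49, SE 0.12), lactate dehydrogenase LDHA at 150 against 353 FPKM (log2 -1.23, SE 0.22) and the interferon-induced IFIT1 at 2.93 against 7.83 FPKM. NKX2-1 was lower in the library labelled IWP2 by a log2 of -0.71 (SE 0.12) with intervals apart, SOX2 by -0.42 (SE 0.04) and FOXA2 by -0.28 (SE 0.07). AXIN2 had a log2 ratio of 0.00 (SE 0.21), and the intervals of NKD1, NOTUM, LEF1 and SOX9 overlapped. SP5 was listed at 0 in both.

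No member of the Wnt or lung lists was 2-fold apart between these libraries. Their medians were -0.17 (percentile 1.08) and -0.30 (percentile 0.03), or -0.04 and -0.14 as TPM. Cell cycle genes had a median log2 of -0.34 (percentile 0.01) and BMP targets one of -0.38 (percentile 0.02), or -0.17 and -0.21 as TPM. Mesenchymal genes had a median of -0.02 (percentile 74.5), of either sign by scaling, with POSTN at 3.33 against 8.01 FPKM and DCN at 15.4 against 37.1 FPKM. Of 16367 genes, 292 were at least 2-fold higher and 308 lower, and the intervals lay apart for 34 and 52. Unchanged simulated libraries gave 312 and 293 on average and at most 352 and 327, so the counts of 2-fold differences lay within what quantification noise gave. With intervals apart they gave 18.7 and 15.7 on average and at most 30 and 23. Higher genes were 48.7% of the calls, or 60.5% as TPM.

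The day 15 and day 12 controls were compared for differences with time in culture. Cells analysed on day 15 had been replated on day 10, and the labels do not say whether the day 12 control was. Time and replating can thus not be told apart here. Genes of the cell cycle had the lowest median at day 15, -0.71 (percentile 0.00), with 6 of 21 at least 2-fold lower, including the replication helicase subunits MCM6 at 19.8 against 52.6 FPKM (log2 -1.36, SE 0.06) and MCM4 at 40.5 against 86.6 FPKM, and E2F1 at 5.48 against 15.3 FPKM. MYC was at 8.70 against 26.0 FPKM (log2 -1.48, SE 0.10). The p53 and stress list had a median log2 of 0.41 (percentile 100), with the cell cycle inhibitor CDKN1A at 69.2 against 25.4 FPKM (log2 1.41, SE 0.07), GDF15 at 56.9 against 23.7 FPKM and FAS at 8.63 against 2.90 FPKM. Pluripotency genes had a median of -0.47 (percentile 0.05), with LIN28A, an inhibitor of let-7 processing, at 24.5 against 94.1 FPKM (log2 -1.90, SE 0.05). BMP targets stood at -0.46 (percentile 0.01), with SMAD6 at 11.6 against 28.1 FPKM, and FGF targets at -0.35 (percentile 0.29). Mesenchymal genes had a median log2 of 0.49 (percentile 100), with lumican, LUM, at 128 against 22.1 FPKM (log2 2.48, SE 0.08) and COL3A1 at 56.9 against 24.1 FPKM, while TAGLN was at 69.0 against 221 FPKM. Over members at 1 FPKM or more the medians were 0.98 for mesenchymal and -0.72 for pluripotency genes.

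Wnt targets, at -0.05 (percentile 14.5), and lung progenitor genes, at -0.05 (percentile 47.9), lay within the random lists between the controls, and were at -0.14 and -0.12 over members at 1 FPKM or more. NKX2-1 was lower at day 15 by a log2 of -0.49 (SE 0.05), FOXA2 by -0.26 (SE 0.06) and SOX9 by -0.21 (SE 0.06), whereas SOX2 was higher by 1.15 (SE 0.06) and NOTUM by 0.78 (SE 0.23). The intervals of AXIN2, NKD1, SP5 and LEF1 overlapped. Alveolar genes had a median of 0.16 (percentile 98.0), but -0.08 over the 7 members at 1 FPKM or more. The 8 highest genes were CRH, AGR2, AGR3, LUM, NELL1, C9orf135, SSXP10 and AKR1C1, with CRH at 23.5 against 1.68 FPKM (log2 3.19, SE 0.14) and AGR2, a disulfide isomerase of secretory epithelia, at 25.5 against 1.97 FPKM. The 8 lowest were NPPB, MYL7, LIN28A, ANKRD1, STC2, HPR, SLC2A3 and ACTC1, with the natriuretic peptide gene NPPB at 3.62 against 45.6 FPKM (log2 -3.33, SE 0.20) and ANKRD1 at 80.6 against 287 FPKM. AKR1C1, HPR and SLC2A3 have close paralogs with which fragments can be shared. Of 15926 genes, 476 were at least 2-fold higher and 403 lower, with intervals apart for 209 and 179, where unchanged simulated libraries gave 253 and 255 on average, and 15.8 and 14.1 with intervals apart.

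The authors' deposited table of gene differences tests each pair of 4 libraries that it names d12, d15, d15c and d15Iwp2. With 1 library per group, its calls do not measure the spread between cultures. Many called rows share the smallest p-value of the table, so a q that they have in common does not rank them. Which of d15 and d15c is the day 15 control is not stated, so only the pair of both was matched to a comparison, without a direction. Between d15 and d15c, the authors' deposited table called 131 genes different, with the row of NKX2-1 and SFTA3, SP5, TPPP3, SERPINA1, AFP, TP63, HHEX, CYP1A1, CDH6 and SCGN at a q of 0.0113 each. WIF1 was called at a q of 0.0458 there. SOX2 (q 0.757), NKD1 (q 0.279), CPM (q 0.158), HNF4A (q 0.0876) and APCDD1 (q 0.0640) were not called in the authors' deposited table, nor were NOTUM, LEF1, SOX9, FOXA2 and the row that AXIN2 shares with CEP112. Of the 8 highest and 8 lowest genes of the library labelled CHIR99021, 4 and 6 were called in the authors' deposited table. It called 6 genes between d15c and d15Iwp2, 139 between d15 and d15Iwp2, 21 between d12 and d15, 171 between d12 and d15c and 188 between d12 and d15Iwp2.

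In the authors' deposited table of transcript isoforms no isoform was called in any of the 6 pairs. Between 59498 and 60856 isoforms were tested per pair, and the smallest p-value was the same in all pairs. Such a common lower limit over so many tests can leave none called, so this does not show that isoforms were unchanged. In the authors' deposited table of start-site groups 49 were called between d15 and d15c and 65 between d15 and d15Iwp2. For the d15 and d15c pair, of the groups of NKX2-1, LEF1, TCF7, TP63, SOX2, SOX9, FOXA2 and AXIN2, 1 group of TP63 was called in the authors' deposited table and none of the others. For the d15 and d15Iwp2 pair it called 1 group each of NKX2-1 and TP63.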

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

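No paired analysis was possible because each group had 1 library, and no library could be left out. Protein-coding genes alone, and the alternatives for lists other than Wnt targets and lung genes, were chosen after the data had been seen. Under the pseudocount of 0.1, the common median and TPM, no named gene with intervals apart changed its direction. The Wnt medians kept theirs under the common median and TPM, although that of the library labelled IWP2 against the day 15 control was -0.23 as TPM in place of -0.42, and that of the library labelled CHIR99021 -0.32 under the common median in place of -0.21. With members at 1 FPKM or more alone, the alveolar medians changed sign against the day 15 control (0.40 in place of -0.04 and 0.15 in place of -0.22 for the libraries labelled CHIR99021 and IWP2) and between the controls (-0.0801 in place of 0.16). Between the treated libraries the pan-epithelial median was 0.12 as TPM in place of -0.05. The lung median against the day 15 control was -0.06 in place of 0.06 under the common median for the library labelled CHIR99021, and 0.12 in place of -0.10 as TPM for that labelled IWP2, both inside the random lists. Dropping the FPKM minimum moved no count, since a 2-fold difference on FPKM + 1 needs about that minimum by construction. The alternative chosen at the outset with FPKM from the authors' deposited table was not run, because its library names were not matched. For the library labelled CHIR99021 against the day 15 control, the 608 lower genes became 1019 with a pseudocount of 0.1, 366 at 5 FPKM or more, 319 with intervals apart and 240 when protein-coding. For the library labelled IWP2 against the day 15 control, the 1225 higher genes became 1903 with the pseudocount of 0.1 and 2106 as TPM, and the 856 lower genes became 562 with intervals apart and 431 when protein-coding. Between the treated libraries, where unchanged simulated libraries gave 312 and 293, or 147 and 139 at 5 FPKM or more, the 292 higher genes became 541 with the pseudocount of 0.1, 110 at 5 FPKM or more, 497 as TPM, 34 with intervals apart and 26 when protein-coding, and the 308 lower genes became 556, 154, 52 and 60 (pseudocount, 5 FPKM, intervals, protein-coding). Between the controls, the 476 higher genes became 972, 249, 209 and 209, and the 403 lower genes 644, 244, 179 and 159 in that order. Genes higher and lower in both treated libraries became 1232 and 696 with the pseudocount of 0.1. As TPM the median of Wnt targets between the treated libraries was -0.0428 instead of -0.17, and that of lung genes -0.14 instead of -0.30. Stricter limits lower a count by construction, and the cause of the other shifts was not tested. Of 196 named values, 101 moved by more than their SE with the pseudocount of 0.1, 52 as TPM and 37 with a common median. Depth limits the low genes most, and a gene listed at 0 was not detectable rather than absent.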

Other observations

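The 6 gene lists of the next paragraphs, the tests of ribosomal protein genes, the test of lung genes against the day 12 control and that of pan-epithelial genes by themselves were chosen after the results had been seen, while the tests of the treatment label and of pan-epithelial against lung genes were set before the data were seen, and that of all genes apart in both treated libraries before its own result. The genes named from these lists were picked with their values in view. The themes of the 6 lists came from these same values, so their extreme percentiles partly follow from that choice and are no separate support. Genes of the actin cytoskeleton and of its regulators SRF and YAP were higher in both treated libraries than in the day 15 control, with medians of 1.00 and 1.05 (percentile 100 each), and 10 and 11 of 20 members at least 2-fold higher. ANKRD1 was at 287 FPKM in the day 12 control, 80.6 in the day 15 control, 289 in the library labelled CHIR99021 and 301 in the library labelled IWP2. TAGLN took 221, 69.0, 374 and 367 FPKM in the same order, so the day 15 control was the lowest for both. Between the controls this list had a median of -0.54 (percentile 0.00). Cardiac and smooth muscle genes had medians of 0.76 (percentile 100) and 0.31 (percentile 97.8) against the day 15 control and -0.34 (percentile 0.16) between the controls, or 1.68, 1.55 and -1.01 over the 8 of 13 members at 1 FPKM or more, with NPPB at 45.6, 3.62, 58.1 and 51.7 FPKM. A day 15 control that stood apart from the other 3 libraries was predicted to place over 50% of the genes apart in both treated libraries nearer to them at day 12, and 132 of 939 (14.1%) lay there. Time in culture differs between the controls, so the day 12 level need not be that of a further day 15 control. Of the genes with intervals apart that were higher in both treated libraries, 60 of 698 had a day 12 level nearer to the treated mean than to the day 15 control, and of those lower in both 72 of 241 did.

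Plasma proteins of liver and yolk sac had medians of 0.65 (percentile 99.99) and 0.54 (percentile 99.98) against the day 15 control, with 8 and 7 of 18 at least 2-fold higher, or medians of 1.48 and 0.76 over members at 1 FPKM or more, and SERPINA1 and TTR stand in the fixed list of gut organs as well. ITIH2 was listed at 0.314 FPKM in the day 15 control, 37.8 in the library labelled CHIR99021 and 44.3 in the library labelled IWP2, and FGB at 33.6, 160 and 193 FPKM, while TTR was already at 224 FPKM in the control. The list stood at 0.14 (percentile 97.5) between the controls and at 0.12 (percentile 99.6) between the treated libraries. Interferon-stimulated genes had medians of 0.71 (percentile 100) in the library labelled CHIR99021 and 0.20 (percentile 86.3) in the library labelled IWP2, of -0.43 (percentile 0.00) between these libraries and of 0.49 (percentile 100) between the controls. Glycolysis and hypoxia genes had medians of -0.11 (percentile 7.42) and -0.44 (percentile 0.11) against the day 15 control, -0.47 (percentile 0.00) between the treated libraries and 0.31 (percentile 100) between the controls. LDHA was at 452, 553, 353 and 150 FPKM and ENO1 at 1541, 1427, 1028 and 600 FPKM from the day 12 control to the library labelled IWP2. As TPM the medians against the day 15 control for the library labelled IWP2 were 0.39 for interferon-stimulated genes, -0.23 for glycolysis and hypoxia and 0.50 for cardiac and smooth muscle, and between the treated libraries that of plasma proteins was 0.29 and that of ribosomal protein genes -0.19. For the library labelled CHIR99021 the glycolysis median was -0.21 under the common median, -0.06 as TPM and -0.05 over members at 1 FPKM or more.

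The median of Wnt targets was lower in the library labelled CHIR99021 than in the day 15 control, although the label names a Wnt agonist, but 4 of 20 members were at least 2-fold lower and 4 at least 2-fold higher (APCDD1, and DKK1, FZD7 and CCND1, named after their values were seen). Had the label marked presence of the agonist there and its absence in the control, the list was predicted above percentile 95 of random lists, and its value of 0.22 argues against that reading. Withdrawal of the agonist, as the design text has it, was predicted below percentile 5, and 0.22 is consistent with it. With as many members 2-fold higher as lower the list is no uniform readout, and both statements rest on its median. A pair of exchanged libraries, and the spread between cultures, stay open with 1 library per group.

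NKX2-1, SFTA3, CPM, ETV5, IRX1, IRX2 and IRX3 were at least 2-fold lower in both treated libraries, and these are 7 of the 22 lung progenitor genes. In each treated library 4 members of that list were at least 2-fold higher than in the day 15 control. FOXA1, FOXP1 and FOXP2, named after their values were seen, were among them in both. From the day 15 control to the libraries labelled CHIR99021 and IWP2, FOXA1 took 23.7, 50.4 and 51.1 FPKM. FOXP1 took 13.8, 36.3 and 32.8 FPKM and FOXP2 0.517, 2.33 and 3.77 FPKM. A lower share of epithelial cells may give the lower levels of the 7 genes, and mesenchymal genes went with it (percentile 98.6 and 100). At an unchanged level per epithelial cell it would lower pan-epithelial genes too. Their medians of 0.83 and 0.53 lay at percentile 99.8 or above, as deposited and under both scalings. EPCAM was at 393 FPKM in the day 15 control, 392 in the library labelled CHIR99021 and 388 in that labelled IWP2. CLDN6 took 260, 696 and 672 FPKM in the same order. A rise of such genes within cells could hide a lower share, so these medians do not exclude one. They also lay above the median of the whole lung list by 0.77 and 0.62, more than the 0.39 and 0.43 that 95% of random lists span to either side, which says less, because members of that list went both ways. A day 15 control that stood apart from the other 3 libraries would place the day 12 level of the 7 genes near the treated ones, and 0% of them lay there, while 6 of the 7, which are not independent of each other, had a day 12 interval above those of both treated libraries. The day 12 control was taken earlier in culture, so it does not show where a further day 15 control would lie. The treatment, acting within the lung epithelium or on which epithelial cells were present, stays open and was not tested. A lower epithelial share hidden by a rise of pan-epithelial genes stays open too. The median of the lung list as a whole lay within the random lists.

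Ribosomal protein genes were lower in both treated libraries, with medians of -0.76 and -1.17 against the day 15 control (percentile 0.00 each) and 7 and 55 of 86 at least 2-fold lower, and they were -0.36 between the treated libraries (percentile 0.00) and 0.37 between the controls (percentile 100). Poorer recovery of short transcripts could lower them, but genes matched on FPKM and transcript length had medians of -0.09 and -0.34, less than 50% of the difference. As matched here, length can thus be a part and not the whole. The match was tighter on length than on FPKM and used 243 genes at 50 FPKM or more. How closely FPKM matched was not measured. Scaling of the libraries left the list low, with a median nearest 0 of -0.70 under the common median and TPM. Against the day 12 control the medians were -0.41 and -0.77, below the range of 95% of the random lists. A day 15 control with an unusually high share would thus explain a part only, provided that the day 12 level stands for that of a usual day 15 control. The day 12 control was taken earlier in culture, so this cannot be decided. The treatment, and a state of the cultures that goes with it, stay open as untested explanations. An unusual day 15 control stays open as well, since there was no further day 15 control to compare.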
